A study of Mus musculus with 6 samples.

How the data were processed

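Circular RNAs (circRNAs), closed RNA loops formed when a downstream splice site joins an upstream one, were measured in kidney cortex of male mice. Per the labels, 3 samples came from normal cortex and 3 from cortex with diabetic kidney injury (DKI). Total RNA was extracted with Trizol, amplified with random primers and labelled with a single green dye, Cy3, per the labels' protocols. Each sample was hybridised to its own one-colour Arraystar circRNA array. The labels carry text that does not match the samples: the growth and treatment fields speak of liver tumour surgery, and the design field of a human array, while the organism field, the array header and the probe set are those of the mouse. The groups used here rest on the sample titles, which state kidney cortex and the group. Nothing in the labels says that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

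Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1. The deposited spot values are intensities, a processed signal after background subtraction and the median raw brightness of the spot and its local background, with flags for spots well above background, saturated or non-uniform. They were not yet normalized between arrays. The authors also deposited a table of log2 values for 14150 circRNA probes. Its columns have nearly the same distribution, with medians from 6.12 to 6.16, and a reference level or centring is not given in the sources used here. It was used as an alternative only. Set against the scanner signals by rank, its 3 DKI columns matched their own arrays best, with rank correlations of 0.997 to 0.999. Its 3 normal columns each matched another normal array best, with rank correlations of 0.996 to 0.998 against 0.945 to 0.964 for their own. The groups are not touched by this, but the replicate numbers of the normal samples differ between both sources. The scanner files were followed here.

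Each array held 14236 circRNA probes with a single spot each, 50 probes with an mRNA accession and 10 spots each, and control probes. Values were log2 processed signals minus the 75th percentile of the array's circRNA probes, as fixed before the data were examined. Control spots were left out of the tests, and outlier spots were left out where a probe had other spots. A circRNA was tested if it was well above background on at least 3 of the 6 arrays, which kept 14119 and left out 117. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all circRNAs tested and a threshold of 0.05. No fold change minimum was set. The same fit was made on the 50 mRNA probes, adjusted over those 50. That comparison was added after the data had been seen. Mouse RefSeq transcripts of assembly GRCm38.p6 gave 44 of the 50 accessions a symbol and left 6 without one, and no coordinates were taken from it.

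The files give circRNAs by probe ID and do not pair these with host genes. The planned tests of host gene lists, circRNA classes and circRNAs of one host gene were therefore not run, and at most 2 IDs are printed in each direction. The planned rule for naming circRNAs, with fewer than 10 past the threshold, took the 12 higher and 12 lower with the smallest unadjusted p. Of the 28 gene lists fixed beforehand, 5 hold genes measured by the mRNA probes, 7 genes in all, and 23 hold none: the lists of proximal tubule, loop of Henle and distal tubule, collecting duct, podocyte, endothelial, mesangial and fibroblast, immune, erythroid, hepatocyte, and adipocyte and adrenal markers, and 13 of the pathway lists. The mRNA probes named were chosen after their values were seen.

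The fit was tested on simulated data with the means and spreads of the 14119 circRNAs and 200 of them changed. With the spread of all 6 arrays it recovered 0.0% of 2-fold, 61.0% of 4-fold and 92.0% of 8-fold changes. With the spread of the 5 arrays without DKI replicate 3 it recovered 7.5%, 99.0% and 99.5%. False calls, of unchanged circRNAs, numbered 8, 27 and 21 there, against 15, 198 and 199 true calls. With the spread of all 6 arrays they numbered 0, 6 and 12, against 0, 122 and 184 true calls. Without DKI replicate 3 the false share was thus above what the threshold aims at, in a single draw for each fold change. At 8-fold it was also above that with the spread of all 6 arrays. The noise was drawn separately for each probe, without differences between arrays that many probes share. The simulation therefore bears on the real counts, also those without DKI replicate 3, only as a caution. Scan session and slide come from the scanner headers. Session 1 held normal replicate 1 and the 3 DKI arrays, and session 2 held normal replicates 2 and 3. Slide 1 held normal replicate 1 and DKI replicate 1, slide 2 normal replicates 2 and 3, and slide 3 DKI replicates 2 and 3. A session block therefore compared the DKI arrays with normal replicate 1 alone. A slide block compared DKI replicate 1 with normal replicate 1 alone. Alternatives covered background correction (normexp with an offset of 50, on median spot brightness, since mean brightness is not a column used here), scaling, the filter on dim probes, the authors' values, an intensity trend, array weights, the replicate number, session or slide as a block, each array left out and other thresholds. Fits without DKI replicate 3 under those choices, within session 1, and with the brightness of control spots as a covariate were added after the data had been seen. The number of arrays limits the precision of all values.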

Results

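The study screened for circRNAs that differ between normal mouse kidney cortex and cortex with diabetic kidney injury (DKI), with 3 arrays per group. Between 13777 and 14160 of the 14236 circRNA probes were well above background on an array, 96.8% to 99.5%, and no circRNA spot was saturated. Between 4.07% and 15.3% of the circRNAs tested lay at or below the mean of the array's negative control probes. The 75th percentile of the circRNA signal was 111.5, 132.6 and 96.7 on the normal arrays and 218.5, 158.6 and 92.3 on DKI replicates 1, 2 and 3. The bright-corner control spots of the array maker had median signals of 33156, 61512 and 39258 on the normal arrays, and of 76690, 67712 and 9317 on the DKI arrays. All values below are log2 signals relative to the 75th percentile of the same array. A probe's value was compared between arrays, and with other probes only to place it against the negative control probes.

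Across circRNAs, normal arrays correlated with each other at r = 0.951 to 0.972, and DKI replicates 1 and 2 at 0.983. DKI replicate 3 stood apart, with r = 0.787 and 0.807 to the other DKI arrays and 0.806 to 0.883 to the normal arrays. These correlations run over probes, which are not independent replicates. The first principal component held 59.9% of the variance. The median SD of a circRNA was 0.26 between normal arrays, 0.51 between the 3 DKI arrays and 0.17 between DKI replicates 1 and 2. The last value rests on 2 arrays and the others on 3, so it is not directly comparable with them.

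**Figure D1:**
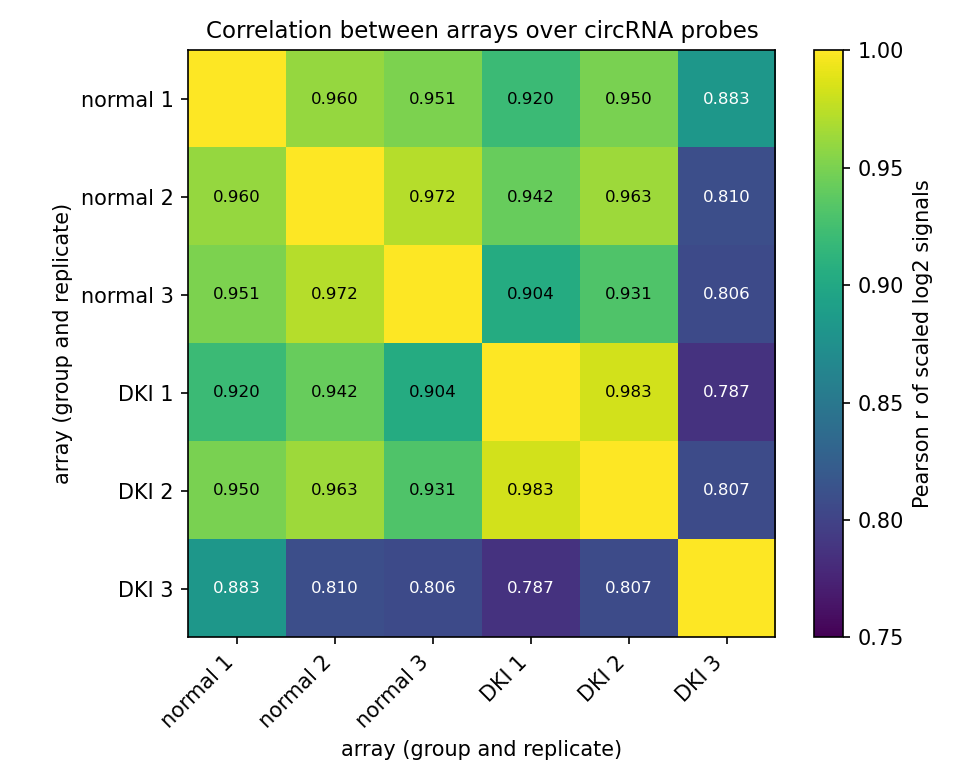
Pearson correlation of scaled log2 signals between each pair of arrays over 14119 circRNA probes, with group and replicate on both axes and colour for r. All pairs without DKI replicate 3 lie between 0.904 and 0.983, and pairs with it lie between 0.787 and 0.883.

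The circRNA with the smallest p, ASCRP4007684, had a scaled log2 signal of 2.80 ± 1.04 (SD, n = 3) in normal cortex and -1.36 ± 0.48 in DKI cortex. The difference was -4.17 (SE 0.55, 95% interval -5.45 to -2.88), 18.0-fold lower in DKI, and all 3 DKI arrays lay below all 3 normal arrays. ASCRP4013568 differed by -1.42 (SE 0.27), 2.68-fold lower in DKI. In the other direction, ASCRP4012382 differed by 1.62 (SE 0.29), 3.07-fold higher in DKI, and ASCRP4005836 by 1.78 (SE 0.34), 3.43-fold higher. These 4 were well above background on all 6 arrays, yet none passed the adjustment over 14119 circRNAs (limma, adjusted p = 0.482 for each). After normexp background correction and the 75th percentile the differences of ASCRP4007684, ASCRP4013568, ASCRP4012382 and ASCRP4005836 were -3.24, -0.66, 0.74 and 0.90. With scan session as a block the differences were -3.68, -1.12, 1.60 and 1.85, with an adjusted p of 0.993 for each. Within slide 1, DKI replicate 1 differed from normal replicate 1 by -3.22, -1.19, 1.74 and 1.91, with no replicate. The same 4 passed without DKI replicate 3, at adjusted p from 0.0253 to 0.0265, in a fit to 5 of the 6 arrays they were picked on. The 12 higher circRNAs with the smallest p differed by 1.11 to 1.83 and the 12 lower ones by 1.15 to 4.17 in size. In all of them the arrays of both groups were fully separated, which a pick by the smallest p on these same arrays favours.

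Over all 6 arrays limma called 0 circRNAs, with a lowest adjusted p of 0.482. At an unadjusted p under 0.05 there were 1459, of which 485 were higher and 974 lower in DKI, where 706 would be reached with no change at all. The arrays of both groups did not overlap for 2810 circRNAs, 19.9% against the 10% that chance gives. Of these, 876 were higher in every DKI array and 1934 lower. Neither 706 nor 10% allows for differences between arrays that many probes share. Splitting the same 6 arrays another way gave 2286 at an unadjusted p under 0.05. After scaling, 14 of the 15 negative control probes also had all DKI arrays below all normal arrays. Array weights gave 6112 calls, control spot brightness as a covariate 1290 and an intensity trend 0. A session block and session 1 alone both set the 3 DKI arrays against normal replicate 1 only. Neither was therefore a check of the count over all 6 arrays. DKI replicate 3 decided the count: without it limma called 1345 circRNAs, 1045 higher and 300 lower in DKI, 9.53% of those tested.

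Among the 1045 circRNAs called higher without DKI replicate 3, the median difference was 1.27, and in DKI replicate 3 itself the median was -0.53 relative to the normal mean. Only 273 of them, 26.1%, lay above the normal mean in that array, against 49.6% of all circRNAs tested. Of the 300 called lower, with a median difference of -1.01, 208 or 69.3% also lay below the normal mean in DKI replicate 3. In both directions together 35.8% had the same sign. Simulated arrays with no change gave 74.3% on average, from 72.0% to 76.0% over 20 simulations. There the picks came from noise alone and shared their normal arrays with the array checked. The 74.3% is therefore not the level an unchanged array would give for circRNAs that truly differ in the other DKI arrays. No conclusion was drawn from setting 35.8% against it. With a session block or within session 1, normal replicate 1 alone then stood against DKI replicates 1 and 2. Both fits estimate the same difference and differ only in how the spread is estimated. Neither is therefore a separate check on the count without DKI replicate 3. It was 0 when DKI replicate 1 or 2 was left out as well, 2771 without normal replicate 1, 371 without normal replicate 3, and 1 with control spot brightness as a covariate. Quantile normalization gave 1177 calls, 89.3% of them higher, and normexp with quantile normalization gave 79, 93.7% of them higher, against 77.7% with the 75th percentile. The share of higher calls varied among the larger sets. It was 74.3% of 1718 with an intensity trend and 73.4% of 1606 over probes well above background on all arrays. It was 51.8% within session 1, with its single normal array, 52.8% without normal replicate 1, 54.5% of 3414 at an adjusted p under 0.10, and 49.5% of 4349 at an unadjusted p under 0.05 with at least 1.5-fold.

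Among the 50 mRNA probes, Ppara, the nuclear receptor that switches on fatty acid oxidation genes, had the smallest p. Its signal was 0.76 ± 0.46 (SD, n = 3) in normal and 2.74 ± 0.92 in DKI cortex. The difference was 1.98 (SE 0.47, 95% interval 0.89 to 3.06), 3.94-fold higher in DKI, and each DKI array lay above each normal array, by 1.21, 1.73 and 2.99 relative to the normal mean. Over all 50 probes it did not pass (limma, adjusted p = 0.143). Cpt1a, which loads long-chain fatty acids for import into mitochondria, differed by 0.59 (SE 0.28) and was also higher on each DKI array than on each normal array (adjusted p = 0.362). Its difference was smaller with normexp, 0.20 with the 75th percentile and 0.28 with quantile normalization. In the list of fatty acid and lipid metabolism, with 72 genes, these 2 were the measured members. Of them, 1 passed when adjusted over the list alone (Ppara, limma adjusted p = 0.00573), and 0 passed over all 50. With a scan session or slide block 0 passed over the list alone. With the session block the Ppara difference was 1.72, with an adjusted p of 0.711 over all 50, and 0.95 within slide 1. DKI replicate 3, the array that stood apart, had the highest Ppara signal.

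The other lists held 1 or 2 measured genes, and 0 of these passed, over all 50 or adjusted over the list alone. In glucose metabolism, Gpi1, the isomerase of glucose 6-phosphate, differed by 0.61 (SE 0.30). In oxidative stress defence, the glutathione transferase Gsta4 differed by -0.88 (SE 0.44) and the peroxiredoxin Prdx2 by -0.19. Without DKI replicate 3 these were -0.49 and -0.39, and without DKI replicate 1 Prdx2 was -0.016. In TGF-beta and BMP signalling, the decoy receptor Bambi differed by -0.41, and by -0.14 without DKI replicate 1. All its spots were well above background, but its signal lay near that of the negative control probes, whose own mean differed by -0.74. In autophagy, Atg3, an enzyme of LC3 lipidation, differed by -0.75. Atg3 had the opposite sign with a session block, 0.0155. Outside the lists, Pex11a, a peroxisome membrane protein, differed by -0.80 (SE 0.29), Gamt, the last enzyme of creatine synthesis, by -0.66 (SE 0.25), and Anxa8, an annexin, by -0.78 (SE 0.28), each lower on all 3 DKI arrays than on all normal arrays (limma, adjusted p = 0.229 for each). Mbp, a myelin protein, differed by -0.97, but it too lay near the negative control probes, and on at least 1 array only 0.3 of its spots were well above background. Limma called 0 of the 50 mRNA probes, and 6 had an unadjusted p under 0.05, 1 higher and 5 lower.

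Without DKI replicate 3, limma called 13 mRNA probes, 5 higher and 8 lower in DKI. H2-Q7, a class Ib histocompatibility gene with close paralogs whose transcripts its probe may share, was the most different: DKI replicates 1 and 2 lay 2.41 and 2.61 above the normal mean (adjusted p = 0.000191), and DKI replicate 3 lay at -1.94 relative to it. Actb, the cytoplasmic actin often used as a reference, went the same way, 0.90 above in replicates 1 and 2 and -0.97 in replicate 3. So did the 14 circRNA control probes of the array maker, by 1.55, 1.17 and -1.28 on average in replicates 1, 2 and 3. Ppara (1.47, adjusted p = 0.0324), Cpt1a (0.73, adjusted p = 0.0494) and Acaa2, a thiolase of mitochondrial fatty acid oxidation (0.81, adjusted p = 0.0418), were the other 3 higher ones, and DKI replicate 3 lay above the normal mean for each. Among the 8 lower ones the olfactory receptor gene Olfr1307 had the smallest p (-0.86, limma adjusted p = 0.0408). A probe without a symbol (-1.18) and Alkbh4 (-0.73) followed, each at an adjusted p of 0.0418. The 8 also included Gamt (-0.71), Chgb, a secretory granule protein (-0.71), and the cell cycle factor E2f1 (-0.64), each at an adjusted p of 0.0494. For 4 of the 8, among them E2f1, DKI replicate 3 lay above the normal mean. The E2f1 signal was not far above the negative control probes, which differed by -0.70 between DKI replicates 1 and 2 and the normal arrays. The count of 13 was 1 when DKI replicate 1 or 2 was left out as well, 5 without normal replicate 2 and 2 without normal replicate 3. It was 7 with quantile normalization, 21 with normexp and the 75th percentile, 17 of them lower, and 1 with control spot brightness as a covariate. A slide block compared DKI replicate 1 with normal replicate 1 alone, and each probe's own spread came from normal replicates 2 and 3. Its count, and that within session 1 with a single normal array, are not set beside these.

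**Figure D2:**
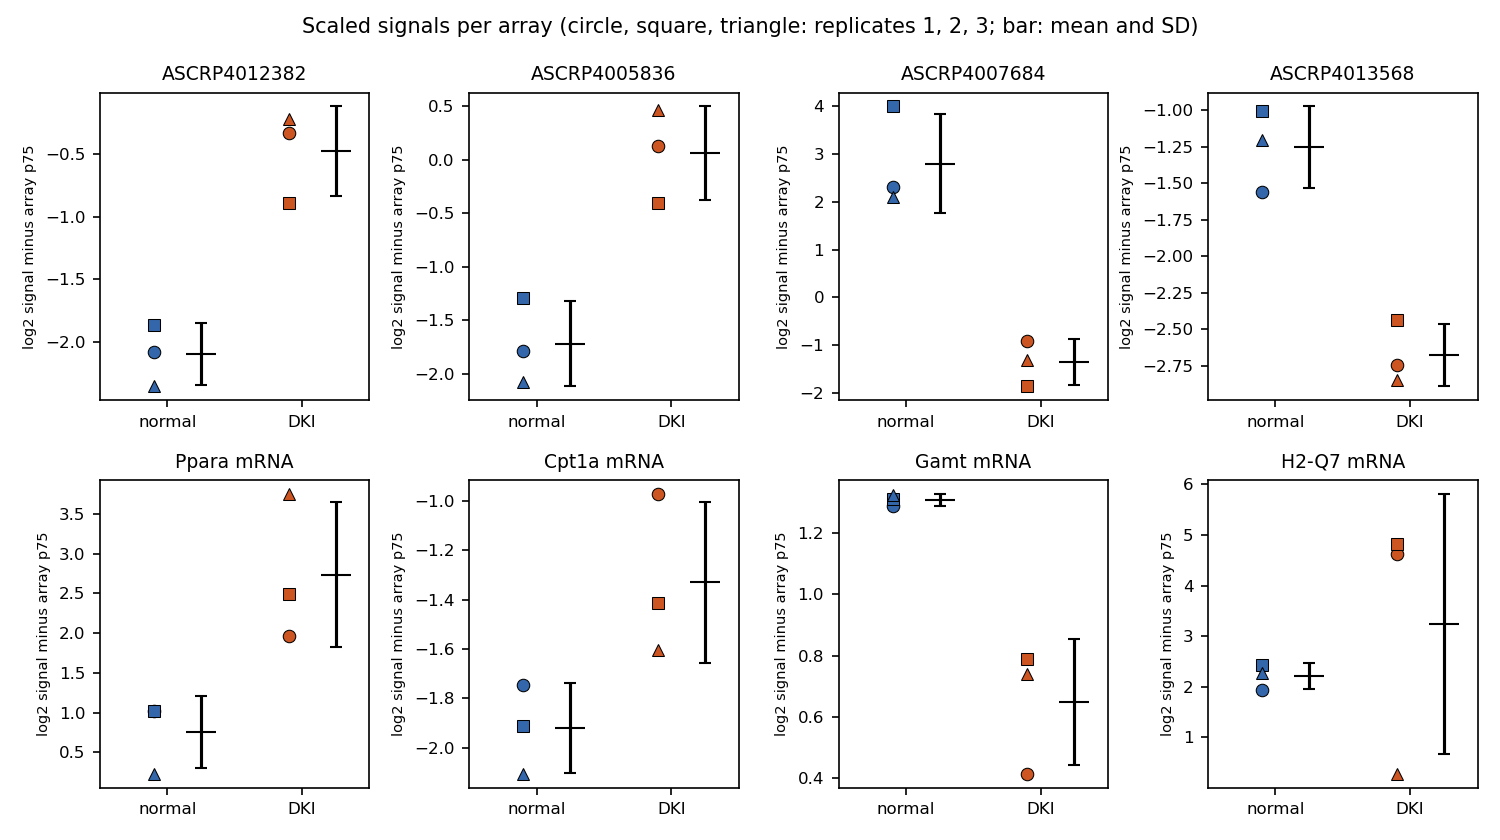
Scaled log2 signal (log2 signal minus the 75th percentile of the array) of 4 circRNAs and 4 mRNAs in normal and DKI cortex, with a symbol per replicate and the mean and SD of 3 arrays beside them. The groups do not overlap for the circRNAs, Ppara, Cpt1a or Gamt, and H2-Q7 of DKI replicate 3 lies at 0.28, below the normal arrays.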

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

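With all 6 arrays, the count of 0 circRNAs held under quantile normalization, normexp, the other percentile set, median scaling, both filters on dim probes, the authors' values, an intensity trend, a session or slide block, and a threshold of 0.10. It also held under the replicate block (0 calls, 766 at an unadjusted p under 0.05). By the scanner numbering, only the arrays numbered 2 deviated together and matched each other best (r = -0.42, 0.39 and -0.10 for replicates 1, 2 and 3), so the numbers were not taken to pair the samples. Array weights gave 6112 calls (2620 higher, 3492 lower). There DKI replicate 2 carried a weight of 14.9 and DKI replicate 3 of 0.0735, and the weights did not converge. An unadjusted p under 0.05 with at least 1.5-fold gave 1435 (476 higher, 959 lower). Control spot brightness as a covariate gave 1290 (732 higher, 558 lower). Leaving out 1 array gave 0 to 1345 circRNAs, 0 to 1045 higher and 0 to 300 lower, where each count above 0 came without DKI replicate 3. The cause of these moves was not tested beyond the tests given under the other observations. The values without DKI replicate 3, within session 1 and with the covariate, and all on mRNA probes, were chosen after seeing the data.

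The 1345 calls without DKI replicate 3 became 79 with normexp and quantile normalization, all 79 among the 1345, 3522 with array weights, 826 with the replicate block, 3 with a session block, 0 with a slide block, 3141 within session 1 and 1 with control spot brightness as a covariate. They became 3414 at 0.10 and 4349 at an unadjusted p under 0.05 with at least 1.5-fold. Leaving out a further array gave 0 (DKI replicate 1 or 2) to 2771 (normal replicate 1), and 371 without normal replicate 3. A lone array was then assumed to vary like the rest. The share of higher calls was 66.2% with normexp and the 75th percentile, 89.1% with the authors' values and 52.9% with array weights.

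The count of 0 mRNA probes became 5 with array weights, 1 with the replicate block (Ppara, adjusted p = 0.0106, from 0.00020 to 0.885 over its alternatives), 11 with the brightness covariate and 6 at an unadjusted p under 0.05 with at least 1.5-fold. Leaving out 1 array gave 0 to 13, the latter without DKI replicate 3. Those 13 became 0 with the replicate block and 37 with a slide block (28 lower). Ppara and the 4 named circRNAs kept their direction, but the circRNA differences were smaller with normexp (ASCRP4013568 -0.53 and ASCRP4007684 -3.15 with quantile normalization). The cause was not tested. Atg3 turned to 0.0155 with a session block and within session 1 and to 0.62 with a slide block. Actb turned to -0.0725 with a session block and within session 1, and ranged from -0.0384 to 0.90 with 1 array left out. The host gene list tests, their camera and fry alternatives and the same-host count could not be fitted without host genes. Although 96.8% or more of circRNA probes were flagged well above background on every array, 4.07% to 15.3% of the circRNAs tested lay at or below the mean of the negative control probes of an array, which limits what dim circRNAs can show.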

Other observations

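The tests of spatial position, of a wrong label, of session for each direction, and of splits of the 6 and 5 arrays without a covariate were chosen after their results had been seen for circRNAs; the other tests were written first. The 14 circRNA control probes of the array maker were higher on DKI replicates 1 and 2 than the normal mean, by 1.55 and 1.17 on average, and all 14 were lower on DKI replicate 3, by -1.28 on average. With all 6 arrays the difference was 0.48 (exact two-sided permutation p = 0.7, where 0.1 is the smallest that 3 against 3 can give). After scaling, all 15 negative control probes had a lower mean in DKI, by -0.44 to -1.21, and 14 of the 15 had all DKI arrays below all normal arrays. Their mean was -3.01 ± 0.11 (SD, n = 3) on normal and -3.74 ± 0.12 on DKI arrays (exact two-sided permutation p = 0.1, the smallest possible). This holds for scaled values: before scaling their mean was 3.71, 4.01 and 3.71 on the normal arrays and 3.96, 3.71 and 2.71 on DKI replicates 1, 2 and 3, so DKI replicates 1 and 2 lay at or within the normal range. A probe was well above background on all DKI arrays and on no normal array in 12 cases, and the other way round in 1.

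DKI replicate 3 stands apart from the other arrays, and its control spots were the dimmest. A spatial defect is argued against: a grid of 8 by 8 blocks explained 0.00597 of the variance of its deviation. A wrong label stays open: its highest correlation with a normal array, 0.883, lay below the 0.951 between normal arrays, but above its 0.787 and 0.807 with the other DKI arrays, and a weakly hybridised normal sample would fall low as well. Weak labelling or hybridization also stays open. Over the upper quartile of probes by brightness, its highest rank correlation with another array was 0.669, but the limit of 0.90 set in advance was wrong, since other pairs of arrays fell to 0.719 there. A difference of that sample's tissue, such as a different degree of injury, could also account for it and was not tested.

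The 1345 circRNAs called without DKI replicate 3 were set against technical sources. Scan session as the whole cause was tested on 1000 circRNAs, not on the calls themselves. They were picked on DKI replicate 2 against normal replicates 2 and 3. A share of 0.815 went the same way in DKI replicate 1 against normal replicate 1, other arrays from 1 session and 1 slide. For circRNAs picked as higher the share was 0.96, where 0.397 of all circRNAs were higher in that comparison. This argues against session as the whole cause for those picked as higher. DKI replicate 1 also had brighter control spots than normal replicate 1 (76690 against 33156), so the agreement does not point to injury. For those picked as lower it was 0.67, close to the 0.603 of all circRNAs that were lower there, so scan session stays open for the lower calls. Array brightness may contribute: of the 1045 called higher, a share of 0.878 also lay higher on normal replicate 2, the normal array with the brightest control spots, than on the mean of the other normal arrays, against 0.439 of all circRNAs. Of the 300 called lower, 41.0% did. DKI replicates 1 and 2 had the brightest control spots of all, so brightness and injury cannot be separated by this test, and injury stays open.

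Splits of the arrays were too few for a share under 0.05. For circRNAs at an unadjusted p under 0.05 the real split of 6 arrays gave 1459 and the highest other 2286, and 2 of the 10 splits gave as many. That other split puts the 3 arrays with the dimmest control spots, normal replicates 1 and 3 and DKI replicate 3, against the 3 brightest, which points to a structure of the samples by brightness. For the 5 arrays the real split gave 1345 and the highest other 133, the latter being the split by scan session, and 1 of 10 gave as many. For the mRNA probes at an unadjusted p under 0.05 the real split and the highest other both gave 6, and 2 of 10 gave as many. With control spot brightness as a covariate the real split gave 1290 and the highest other 0, and 1 of 10 gave as many.

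The hypothesis that DKI changes may lie under a brightness effect was looked at with those 1290 circRNAs, 732 higher and 558 lower. The covariate gave DKI replicate 3 a leverage of 0.953, against 0.518 at most for another array, so that array almost alone sets the brightness slope. Without it the same fit, with few arrays left for its coefficients, called 1 circRNA, 0 higher and 1 lower. Of the 1290, 755 were also among the 1345 called without DKI replicate 3 and without the covariate, all in the same direction. Both fits share 5 arrays, so part of this overlap is built in, and how far the list depends on DKI replicate 3 stays open. With the covariate Ppara differed by 1.87 and ASCRP4007684 by -4.13.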
